A study of Homo sapiens with 3 samples.

How the data were processed

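RNA recovered with CTCF, a zinc-finger DNA-binding protein that organises chromatin loops, was measured by PAR-CLIP in U2OS, a human osteosarcoma cell line. In PAR-CLIP, cells take up the nucleoside analogue 4-thiouridine, ultraviolet light crosslinks it to proteins that touch the RNA, the protein is immunoprecipitated, and the RNA that stays attached is sequenced. Per the labels' protocols, cells were pulsed with 400 µM 4-thiouridine for 16 to 24 h and irradiated at 365 nm with 400 mJ/cm2. CTCF was precipitated from nuclear lysates, unbound DNA was digested, and the labelled protein-RNA band was cut from a membrane before library preparation. The labels give 3 samples: 2 biological replicates precipitated with different lots of the same antibody, and a merge of the sequencing data of both. Of these, 1 had a processed file used here, that of the merge. Values for each replicate, an input library, a control immunoprecipitation and RNA abundance in these cells were not analysed here.

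The deposited table holds whole-number counts, one per Ensembl gene, with chromosome, start, end, gene identifier and biotype. Per the submitters' processing notes, the build was hg19 and the tools included Bowtie and bedtools. Their versions and roles are not given in the sources used here. The authors merged both replicates before counting, per the labels. Whether reads, deduplicated reads or T-to-C positions were counted, whether reads that map to several places were kept, and whether strand was used are likewise not given. Every listed gene had a count of 6 or more, so the table lists genes above a floor and a gene that is absent had fewer counts or was not among the features counted. The counts were not scaled for depth or length. They summed to 1322047 over 17201 genes. This sum is not the library size, because reads outside listed genes are left out and, as described next, overlapping genes share reads.

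How the counts were made was examined in the table itself. In 2436 pairs one listed interval lay wholly inside another, and the inner gene had more counts than the outer in 0 of them. Shuffling the inner counts 1000 times gave a median of 340 such pairs and never fewer than 306. Among the 579 pairs whose inner gene is annotated as antisense, the number was also 0. In 224 outer genes with several separate inner genes, the inner counts never summed to more than the outer count (0 genes). The table thus holds what counting over the whole interval, introns included and with strand ignored, would give, and 7014 genes (40.8%) overlapped another listed gene. A read in such a place enters the count of each gene there. For 5 short RNAs the count was larger than the length in bases, so the values are not numbers of separate sites. The intervals need not span a whole gene: that of PRPF8, a large spliceosomal protein, was 0.64 kb long, which is shorter than its coding sequence.

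Identifiers were paired with symbols through a table of Ensembl identifiers, which held 16520 of the 17201. The other 681 identifiers carry no name here, and a gene whose identifier has changed since would appear as absent. Older symbols in the gene lists were looked up through RefSeq synonyms for GRCh38.p14, used for names only. Coordinates are those of the table, in hg19. For the share of annotated genes that were listed, 19124 RefSeq protein-coding genes with exactly 1 Ensembl identifier were used.

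With 1 condition and 1 merged sample there is no comparison between groups and no replicate check. No p-value was computed. Counts carry exact 95% Poisson intervals and shares carry exact 95% Clopper-Pearson intervals. At most, these intervals cover counting error. Those on shares of genes treat the genes as independent draws, which is not an error of the counts. Those on shares of counts treat each count as separate, although overlapping genes share reads. None of the intervals covers variation between cultures, and sequenced molecules amplified by PCR are not independent. The lists of genes (23 of them), the pairs of genes and the rules were set before the data were examined. A list with at least 3 listed genes was described by the percentile of its median count among 10000 random lists of the same size, drawn from the listed genes in the same of 10 length bins. Such a percentile describes these libraries and compares no conditions. Of the 23 lists, 19 had enough genes, and chance alone would place 0.475 of them above the 97.5th percentile. The method was tested on simulated data made from the 17201 genes. Of 100 random lists of 15 genes, 3 lay above the 97.5th percentile and 2 below the 2.5th. When the members' counts were multiplied by 2, 32 of 100 lay above it, and when multiplied by 4, 93 of 100 did. Single genes were set against genes of similar length as a percentile within 50 length groups of the listed genes.

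Named genes are WRAP53 and CTCF, the 10 genes with the highest counts, the next 5 protein-coding genes and the next 5 long non-coding genes, and from each list the 2 highest and the lowest listed members. A further gene fixed in advance, and 1 of the lists, are not reported here. Other genes are marked where they were chosen after their values were seen. Alternatives were count minimums of 10 and 5, counts per kb of interval, leaving out rRNA and snoRNA genes, no length matching or 20 bins, leaving out each list's highest member, and the share of a list's genes at 10 counts or more. That share was placed among random lists of annotated protein-coding genes, listed or not, without matching on length. Genes that overlap no other listed gene, and protein-coding genes alone, were added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.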

Results

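The series asked which RNAs touch CTCF directly in U2OS cells. Counts of RNA recovered by PAR-CLIP of CTCF were available for the merge of 2 biological replicates, as 1 value per gene and without a control precipitation. The values below therefore describe what was recovered with CTCF, not enrichment over the RNA present in the nucleus, and none has a replicate error. In all, 17201 genes were listed with counts between 6 and 6801, a median of 31 and quartiles of 13 and 82. The counts summed to 1322047. There were 14445 genes with 10 counts or more, 3528 with 100 or more and 55 with 1000 or more. At the floor of the table, a count of 6 has a 95% Poisson interval of 2.20 to 13.1, so the order of the lowest genes is not resolved at this depth.

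Most of the summed count lay in intervals of protein-coding genes, with many genes of other classes at low counts. Since overlapping genes share reads, these shares do not give the origin of the RNA. Protein-coding genes made up 12220 of the listed genes, or 71.0% (95% Clopper-Pearson interval 70.4 to 71.7%), and 86.2% of the summed count. Their median count was 43. Of the 19124 protein-coding genes annotated in RefSeq that could be paired with an identifier, 11591 (60.6%) were listed. Pseudogenes followed with 2056 genes, 11.95% of those listed and 4.30% of the summed count, at a median of 14. There were 1423 antisense genes with a median count of 17 and 866 lincRNA genes, long intergenic non-coding RNAs, with a median of 16. They held 3.79% and 3.38% of the summed count. Genes annotated as processed transcripts numbered 351 with a median of 27. Small RNA classes were few. The table held 90 snoRNA genes, which guide chemical modification of other RNAs, 18 miRNA genes and 2 rRNA genes. No gene of the mitochondrial chromosome (0) and no gene of the snRNA or misc_RNA classes (0) was listed. Without genes that overlap another listed gene, a choice made after seeing the data, antisense genes made up 2.76% of the genes instead of 8.27%. Another listed gene overlapped 80.3% of antisense genes and 34.7% of protein-coding genes.

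**Figure D1:**
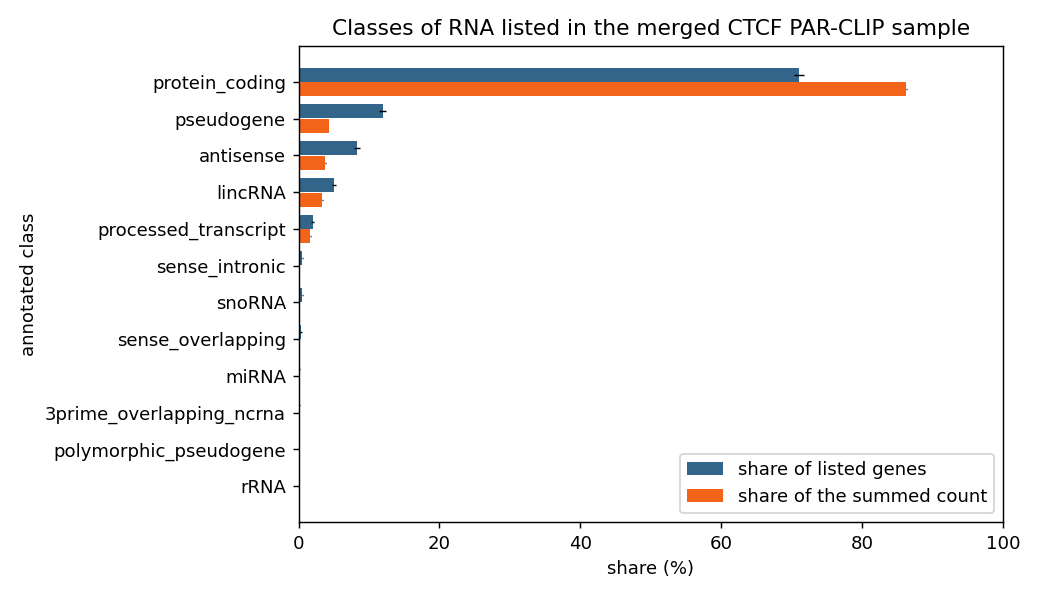
Share of the 17201 listed genes (blue) and of the summed count (orange) in each annotated class, in percent, with exact 95% binomial intervals. The intervals treat genes, or counts, as independent draws and cover no variation between cultures. Protein-coding genes hold 71.0% of the genes and 86.2% of the count, while pseudogenes hold 11.95% of the genes and 4.30% of the count.

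The counts were spread over many genes. The 10 highest genes held 2.84% of the summed count (2.81 to 2.87%), the 100 highest 10.4% and the 1000 highest 38.2%. Counted per kb of gene interval, the 10 highest held 8.86%, with short RNAs and the short ACTB interval ranked first.

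The highest count belonged to MALAT1, an abundant lincRNA of nuclear speckles, with 6801 counts (95% Poisson interval 6640 to 6965) over an 8.71 kb interval on chromosome 11 (65265233 to 65273940). It alone held 0.514% of the summed count. Next came 3 genes for giant cytoskeletal or scaffold proteins. DST, which encodes dystonin, had 5606 counts on chromosome 6 (56322785 to 56507794). PLEC, for the linker protein plectin, had 5026 on chromosome 8 (144989321 to 145013758). AHNAK had 4514 on chromosome 11 (62201016 to 62303579). Genes for cell-surface proteins filled the other places of the top 10. NTM, a neuronal adhesion gene, had 3819 counts over 966 kb of chromosome 11. SDK1, for the adhesion protein sidekick, had 3124 over 968 kb of chromosome 7. TENM2 for a teneurin had 2356, FAT1 for a giant protocadherin 2309, GPC6 for a glypican 2044 and KIRREL3 for an immunoglobulin-type adhesion protein 1957. The next protein-coding genes were MYH9 (1810 counts), SPTBN1 (1799), LSAMP (1701), PARD3 (1697) and AUTS2 (1696). MYH9 and SPTBN1 encode non-muscle myosin heavy chain and a spectrin.

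Among the other long non-coding genes, CYTOR had 1427 counts and MIR4435-2HG 1374. Both lie on chromosome 2 and are near-identical copies over part of their length, so that the authors' alignment could divide their reads either way. LINC02055 had 1180 counts on chromosome 8 and DUXAP9 had 1083 on chromosome 14. ZBTB47-AS1, annotated as antisense, had 950 counts over an interval that overlaps NKTR, which had 949. These shared reads leave open which gene the RNA came from.

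Longer genes had more counts. Spearman's rho between count and interval length was 0.464 across all listed genes and 0.434 across protein-coding genes, which are not independent replicates. Protein-coding genes were divided into 10 equal groups by length. In the shortest group, with a median length of 3.28 kb, the median count was 16. In the longest group, with a median length of 268 kb, it was 114.

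**Figure D2:**
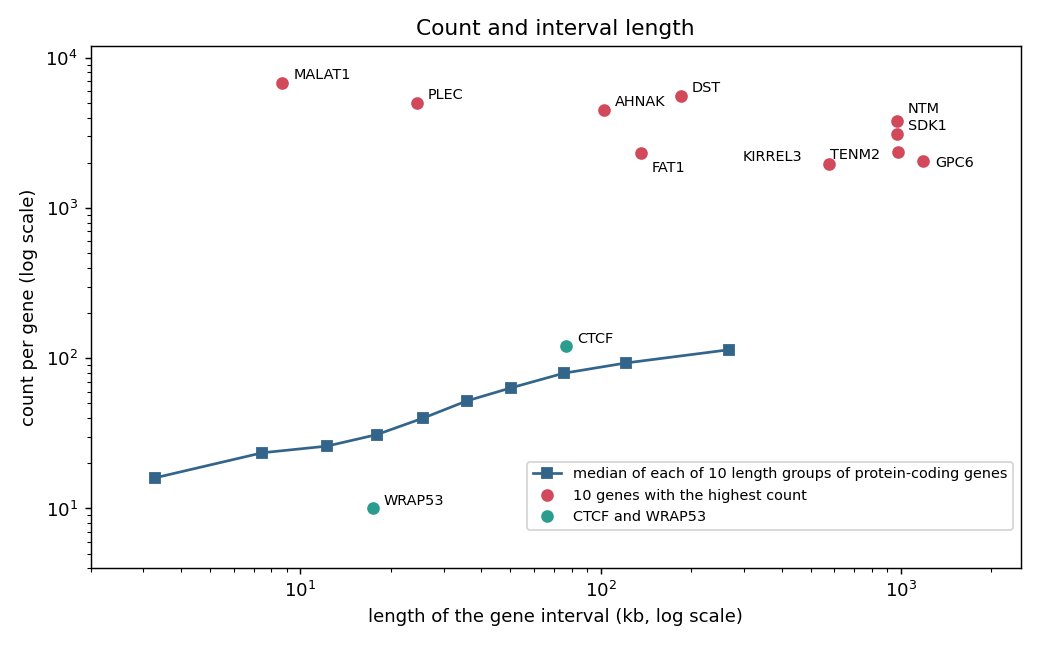
Count per gene against the length of the gene interval in kb, both on log scales. Squares give the median count of each of 10 equal groups of protein-coding genes by length, rising from 16 to 114, and circles give single genes, of which the 10 highest lie between 1957 and 6801. CTCF lies at 120 and WRAP53 at 10.

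CTCF itself had 120 counts (99.5 to 143) on chromosome 16 (67596310 to 67673086), at the 72.4th percentile for its length. WRAP53, for a protein of telomerase RNA trafficking, had 10 counts (95% Poisson interval 4.80 to 18.4) on chromosome 17 (7589389 to 7606820), at the 14.7th percentile for its length. Of all listed genes, 18.8% had 10 counts or fewer. Of the 11 sense and antisense pairs fixed in advance, 2 had both genes listed. In one of them, ZFAS1, a snoRNA host, had 271 counts and ZNFX1, a zinc-finger helicase gene, had 515. ZFAS1 held 34.5% of the pair's counts (31.2 to 37.9%) but 65.8% when counted per kb. Their intervals overlap. Over the 8 listed members of the list of pairs, the median of 44.5 lay at the 58.9th percentile.

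Genes of chromatin architecture and of CTCF's protein partners had high counts. All 18 genes of the list of CTCF, cohesin and related factors were listed, with a median of 233.5 against 40 for random lists of matched length (2.5th to 97.5th percentile 19 to 82.5). NIPBL, the cohesin loader, had 831 counts and SMC1A, a cohesin subunit, 768. YY1, a looping factor, had 6, in an interval of 1.05 kb. In the list of RNA-binding proteins and CTCF partners, 10 of 11 genes were listed, all of them above the median for genes of similar length, and the list's median was 372.5 (random 31.5). DDX5, a helicase, had 1117 counts and HNRNPU, a nuclear matrix protein, 1029. SRA1, a gene for a coactivator RNA, had 50. Both medians exceeded those of all 10000 random lists.

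Genes of RNA processing and of abundant mRNAs also lay above the random lists. The 17 splicing-factor genes had a median of 362 (random 24), led by SON at 1428 and SRRM2 at 1240, both of nuclear speckles. PRPF8 was lowest at 23, over its 0.64 kb interval. The 15 genes of abundant cytoplasmic mRNAs had a median of 274 (random 16). HSP90AB1, a chaperone, had 1424 counts, beta-actin (ACTB) 786 and the ferritin gene FTL 20. The 18 ribosomal protein genes had a median of 116.5 (random 17), with RPL4 at 404, RPL3 at 364 and RPS27 at 6. Among the 15 snoRNA host genes the median was 147 (random 17). NCL for nucleolin had 819 counts, NOP56 425 and SNHG12 30. The percentile was 100 for these 4 lists. When genes that overlap another listed gene were left out, which removed 11 of the 18 ribosomal protein genes, that list moved to the 96.8th percentile.

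Cell-cycle genes were also higher than random lists, with a median of 97.5 over 16 genes (random 26.5). The proliferation marker MKI67 had 1545 counts, TOP2A 285 and E2F1 18. The percentile was 99.99.

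In the list of nuclear long non-coding RNAs, 14 of 20 were listed with a median of 123 (random 32, 99.9th percentile). Below MALAT1 came FTX, a gene of the X-inactivation centre, with 563 counts, and HOTAIR had 6. The 6 others, XIST, TSIX, H19, MEG3, HOTTIP and OIP5-AS1, were absent from the table. Per kb the list lay at the 83.6th percentile. Its share of genes at 10 counts or more was at the 69.7th among lists of annotated protein-coding genes, which are not of its class. Of the 9 genes of the X-inactivation centre, 5 were listed with a median of 54 (percentile 39.1). They included RLIM at 282 and CHIC1 at 30. In the imprinted genes 8 of 16 were listed. These 8 had a median of 257 (random 66.5, 99.8th percentile), with IGF2R at 457, GNAS at 439 and KCNQ1OT1 at 31. The share of imprinted genes at 10 counts or more was at the 36.8th percentile among lists of annotated protein-coding genes. Without overlapping genes the imprinted list's median lay at the 93.8th percentile. The long-gene list had 15 of 16 genes listed and a median of 264 (random 91, 99.5th percentile). PARD3 had 1697 counts, WWOX 867 and NAALADL2 17. The NAALADL2 interval was 98.1 kb long, against a median of 785 kb for the list, so its count covers that interval only. Per kb it lay at the 58.4th percentile, and without overlapping genes at the 72.9th.

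In the snoRNA and scaRNA list, 4 of 14 were listed with a median of 11.5 (40.0th percentile). SCARNA10 had 18 counts, SCARNA7 12 and SCARNA6 7. Of the 4 listed, 3 overlap another listed gene and may hold its reads. SCARNA10 overlaps NCAPD2 (37 counts) and SCARNA7 overlaps KPNA4 (212). The share of this list's genes at 10 counts or more was at percentile 0.825 among lists of annotated protein-coding genes. Those are not of its class and were not matched on length, while its listed genes had a median interval of 0.2555 kb. The 10 listed histone genes of 14 with an identifier had a median of 18 (78.4th percentile). The linker histone genes H1-4 and H1-2 had 63 and 39 counts and H4C3 had 7. None (0) of the 16 housekeeping non-coding RNAs (snRNAs, RN7SK, RN7SL1 and others) and none (0) of the 14 mitochondrial genes were listed. Whether these genes were among the features counted is not given, so no level can be read from this.

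Markers of blood, olfactory, liver and neuronal cells were chosen in advance as a background, and their expression in U2OS was not analysed here. Of 15 blood markers and 12 olfactory receptor genes, 0 were listed. In the liver list 3 of 15 were listed, with a median of 8 (random 30, 2.24th percentile). SERPINA1, the antitrypsin gene, had 138 counts, CYP2E1 had 8 and TF 6. Of 14 neuronal markers 6 were listed, with a median of 44.5 (percentile 19.1). SYT1 had 144 counts over 586 kb, RBFOX3 93 over 393 kb and MAPT 6. Of 18 genes of osteosarcoma and mesenchymal cells, 11 were listed with a median of 164 (random 33, 99.9th percentile). Fibronectin (FN1) had 1277 counts, CD44 632 and the bone phosphatase ALPL 8. The other 7 were absent. Outside overlapping genes that list lay at percentile 91.1. Its share of genes at 10 counts or more was at the 54.9th among lists of annotated protein-coding genes. Of 18 genes in the HOX clusters 11 were listed, with a median of 10 (random 19) at the 3.67th percentile. HOXC6 had 100 counts, HOXC4 84 and HOXA11 6, and HOXC6 and HOXC4 overlap each other and HOXC5.

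**Figure D3:**
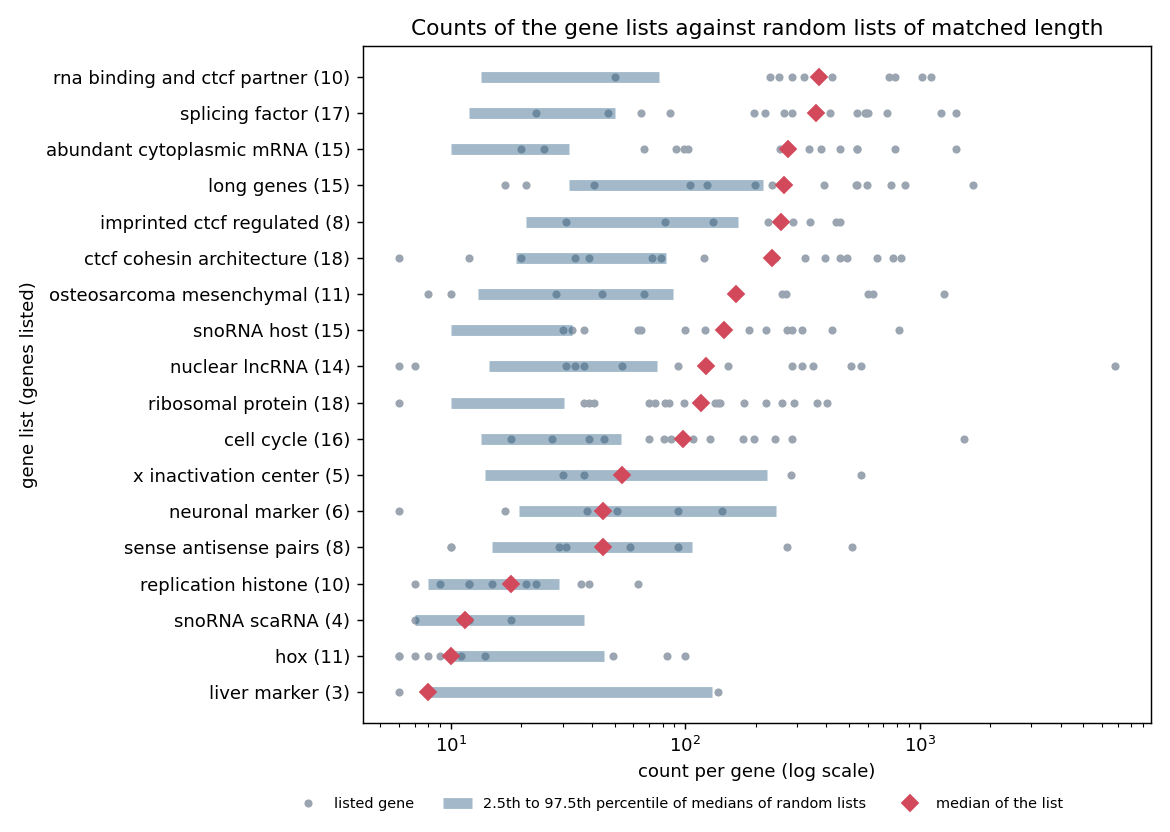
Counts of the listed genes in each gene list (grey circles) with the list's median (red diamond), on a log scale, and the range from the 2.5th to the 97.5th percentile of the medians of 10000 random lists matched on length (blue bars). The number of listed genes is in brackets, and 11 of the 18 lists drawn lie above the range.

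Of the 18 lists described here, 11 lay above the 97.5th percentile and 1, the liver markers, below the 2.5th. Which list lay below depended on the matching: without matching on length the liver list was at percentile 3.335 and the HOX list at 0.55. Lists of well-known genes may favour expressed genes, and the counts could not be set against RNA abundance here, so a high position is not a measure of preference by CTCF.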

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

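The alternatives restricted to genes that overlap no other listed gene, and to protein-coding genes, were chosen after seeing the data. The number of listed genes was 14445 at a minimum of 10 and 17201 at a minimum of 5, since the table starts at 6. The share of the summed count in the 10, 100 and 1000 highest genes moved from 2.84%, 10.4% and 38.2% to 8.86%, 28.6% and 60.7% per kb, and to 4.43%, 14.7% and 49.6% without overlapping genes. Leaving out the 92 rRNA and snoRNA genes kept all 3 within their counting intervals. The snoRNA genes held 0.145% of the summed count and the rRNA genes 0.027%, so this alternative could hardly move the shares. Protein-coding genes were 71.0% of listed genes, 86.2% by summed count, 75.3% at 10 counts or more and 78.4% without overlapping genes. Over all 19 lists, the number above the 97.5th percentile was 12 and ranged from 8, of 16 lists that could be placed without overlapping genes, to 12. The number below the 2.5th percentile was 1. It was 2 with 20 length bins, where the HOX list came to 2.44. By the share of genes at 10 counts or more it was also 2. These were the liver list at 0.01 and the snoRNA and scaRNA list at 0.825. That share was matched on neither length nor class, so the place of the short snoRNA and scaRNA genes says little. For medians without length matching the number was again 1, but the HOX list (0.55) in place of the liver list (3.335). It was 0 without overlapping genes, where too few liver genes were left to place that list. ZFAS1's share of its pair moved from 34.5% to 65.8% per kb, because its interval is shorter. No list changed from above the range to below it. The merged table holds no value for each replicate, so leaving out a replicate was not run, and it holds no T-to-C conversions, so alternatives on them were not run. No paired analysis was possible because only the merged sample was analysed. Depth limits the genes near the floor of 6 counts, WRAP53 included.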

Other observations

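The tests of pseudogenes and of neighbouring genes were set before their results were seen, and the test of length, the gene orders permuted over the whole genome, the spread of windows and all gene families were chosen after the counts had been looked at. Grouping protein-coding genes by the letters that open their symbols gave 143 families with at least 10 listed genes. Their medians were placed among random lists of protein-coding genes matched on length, and 19 families lay above the 97.5th percentile where 3.58 were expected by chance. The 10 CHD genes, chromatin remodellers, had a median of 349.5 (random 60.5). The 10 SRSF splicing-factor genes had 274.5 (random 28), 13 PRPF genes of the spliceosome 162 (random 38), 32 DDX helicase genes 120.5 (random 36) and 31 RBM RNA-binding genes 119 (random 38). Translation was represented by 51 EIF genes at 82 (random 33), and histone demethylases by 16 KDM genes at 153 (random 67.5). The 50 RPL genes were at 55 (random 20) and the 41 RPS genes at 70 (random 24). Families of other functions were also above the range, among them 43 USP genes at 121 (random 58), 11 HSPA genes at 97 (random 28) and 34 KIF genes at 100.5 (random 58.5). At the other end 16 families lay below the 2.5th percentile. The 354 ZNF zinc-finger genes had a median of 22 (random 35.5, 2.5th to 97.5th percentile 31 to 41), the 234 SLC transporter genes 31 (random 45), 27 COL collagen genes 28 (random 64), 29 IL genes of interleukins and their receptors 18 (random 49) and 17 CYP genes 12 (random 34). The random lists were not matched on expression, which was not analysed here.

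Some short or non-coding genes with high counts overlap another listed gene, as in these examples chosen after their values were seen. PLA2G10DP, a pseudogene with 621 counts, overlaps EIF3C with 620. SNORD34 had 105 counts inside RPL13A with 258, and SNORD54 66 inside RPS20 with 138. Of the 3 highest genes annotated as miRNA, the first, with 109 counts on chromosome 7 (5567734 to 5567817), overlaps no listed gene and lies beside the ACTB interval, which ends at 5567729. The next, with 88 counts, lies in the actin gene ACTG1 (458 counts), and the third, with 74, in the actin pseudogene ACTG1P10 (80 counts). The gene RNA5-8SP6, a copy of 5.8S rRNA, had 349 counts over 0.151 kb, the highest count per kb of all, at 2311. It lies on chromosome Y (10037764 to 10037915), whose listed genes summed to 595 counts. Whether its reads came from this copy or from other rRNA copies was not tested.

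A total of 2056 pseudogenes were listed, EEF1A1P5 with 707 counts as the highest, above the 539 of its parent EEF1A1. Reads counted in an overlapping listed interval cannot be the whole cause. Of the pseudogenes, 59.8% (57.7 to 62.0%) overlap no other listed interval, and those had a median count of 13 against 15 for the rest. Listed intervals need not span a whole gene, so a pseudogene inside an unlisted part of a gene also passes as non-overlapping. Reads shared with the parent gene, such as parent reads aligned to a retrocopy, may account for part of the pseudogenes outside other listed intervals. Over 443 parents of 767 such pseudogenes, Spearman's rho between the parent's count and the mean count of its pseudogenes was 0.306 (bootstrap 95% interval 0.221 to 0.391, permuted 97.5th percentile 0.093). Of the 767, 722 were below their parent. That number does not bear on shared reads, because the median parent count was 100 and most pairings would put the pseudogene lower. How the authors treated reads with several alignments stays open, and no biological explanation was tested.

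Counts rose with interval length, and an even spread of reads over the whole interval, as from unspliced precursor RNA alone, was tested as the cause. The slope of the 90th percentile of the count on length, both as log10, was 0.458 (bootstrap 95% interval 0.432 to 0.479) among protein-coding genes, where an even spread at levels that do not change with length would give about 1. Precursor levels that are lower in long genes would also lower the slope, so the bound of 0.6 set for rejecting an even spread does not hold without RNA levels, which were not analysed here. Precursor RNA alone and a mixture of precursor and spliced RNA cannot be told apart, because exons and introns are not separated in counts per gene.

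Whether DNA copy number in this cell line sets a regional level of the counts could not be told. Among 7982 protein-coding genes that overlap no other, the count percentiles for length of genes 5 to 6 Mb apart correlated with a rho of 0.028. This lay within the range of 200 gene orders permuted within chromosomes (0.007 to 0.032), which keep differences between chromosomes, and above the range of orders permuted over the whole genome (-0.015 to 0.011). Genes within 0.1 Mb of each other gave 0.034 (-0.0127 to 0.037 within chromosomes, -0.021 to 0.023 over the genome). The medians of 174 windows of 10 Mb had an SD of 10.3 percentile points, against 7.60 to 9.34 in orders permuted over the genome. Apart from the Y chromosome with 16 genes, chromosome medians over all listed genes lay between 40.0 on chromosome 19 and 59.4 on chromosome 20. With overlapping genes included, the highest window median was 84.9, for 33 protein-coding genes in the first 10 Mb of chromosome 18, and the lowest 29.4, for 21 genes between 20 and 30 Mb of the same chromosome. Copy number itself was not analysed here.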
